A study of Mus musculus with 21 samples.

How the data were processed

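RNA from the hippocampus of 21 male wild-type mice was sequenced in 2 experiments. In the transfer experiment, 4-month-old B6.SJL recipients first received a CD8a antibody on days -11 and -7 to remove their own CD8+ T cells, and then CD8+ T cells by tail vein from donors aged 22 to 28 months (aged T recipients, n = 5) or 3 to 4 months (young T recipients, n = 6). In the depletion experiment, mice aged 22 to 24 months received the CD8a antibody (n = 5) or a rat IgG2b isotype control (n = 5) every 4 days. Mice were perfused, and the hippocampus of 1 hemisphere was used, per the labels' protocols. Libraries were strand-specific, polyA-enriched and paired-end, per the labels' protocols. Each library came from a separately named sample, and replicates were numbered within a group in the order of the sample records, so a number pairs no samples between groups. No duplicates were found: all pairs of libraries within a group differed by at least 7.1 times counting noise (chi-square per degree of freedom).

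The submitters' processing notes name STAR, RSEM and DESeq2 without versions or roles, and the mm10 build. The annotation and counting options are not given in the sources used here. The deposited tables, 1 per experiment, hold 24411 genes by symbol. Per the file headers and the values, each library column holds a normalized signal, the gene's read count divided by 1 size factor per library. The authors' deposited tables also give a log2 fold change with its standard error and p-values from their own DESeq2 comparison, signed as control over treated. Here every fold change is given as aged T minus young T, or CD8a antibody minus IgG2b. Because every value in a library was a whole multiple of 1 step (100% of values, relative tolerance 1e-06), whole reads could be recovered. Library totals were 12361933 to 15055422 reads in aged T recipients and 11232442 to 14911138 in young T recipients. They were 9957822 to 12136146 reads with the CD8a antibody and 11103024 to 14375029 with IgG2b. Detection limits were set at 3 reads and, like read totals, cover counting error only.

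The main tests were chosen before the data were examined. edgeR had been set for read counts and limma for normalized values, and because the tables hold normalized counts the main test was limma-trend (limma 3.58.1, R 4.3.3) on log2(normalized count + 1). Genes with a mean normalized count of at least 10 were tested, each experiment was fitted alone with no covariate, and calls were made at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(normalized count + 1) scale, which understates changes of weakly expressed genes. edgeR 4.0.16 (quasi-likelihood), DESeq2 1.42.0 and limma-voom were run on the recovered reads as alternatives. A set of 43 gene lists, covering T cells, antigen presentation, interferon response, glia, neurons, vessels, neighbouring tissues and metabolism, was written beforehand. The 36 lists with at least 5 tested members in each experiment were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over lists. Each was also tested with the correlation estimated from the data, with fry, and, in a test added after the data were seen, with an exact permutation test of the mean list value per library. Exact tests are two-sided. A score of the mean log2 value of 6 ventral minus that of 4 dorsal hippocampus markers, none of them called in the deposited tables, was added after the data were seen. Signatures of 100 genes per direction with the smallest p were carried from each experiment to the other.

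Genes were named by a rule set beforehand. It took up to 12 genes per direction with the smallest p among called genes, or 5 per direction as not passing where fewer than 5 were called, leaving out symbols of predicted or unnamed genes. From each list with called members it took 4, from each other list that passed it took 2, and it always took a fixed set of T cell, glial, antigen presentation and neuronal genes. Genes named outside this rule are said to be so where they appear, and some genes that the rule takes are not reported here. Coordinates are from the RefSeq annotation of the mm10 build, in which 24290 symbols (99.5%) were found.

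On simulated counts with 100 genes changed 1.5-fold and 100 changed 2-fold, drawn from the means and depths of these libraries, limma recovered 58% and 86% in the transfer design, with 6 false calls among 14142 genes. In the depletion design it recovered 29% and 73%, with 8 false calls among 13933 genes. DESeq2 recovered 63% and 93% in the transfer design with 29 false calls among 18096 genes, and 41% and 78% in the depletion design with 22 false calls among 17920 genes. camera recovered a list changed 1.3-fold in both designs, with 0 false lists. The simulated genes were drawn independently of each other, so this does not cover lists whose members vary together. In the real transfer libraries the estimated correlation of oxidative phosphorylation genes was 0.513. Other splits of the real libraries gave up to 24 passing lists in the transfer and 23 in the depletion.

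Alternatives covered the test, scaling (size factors, trimmed mean of M-values, library size), the pseudocount, the filter on low values, choroid plexus expression as a covariate, the correlation used for lists, and leaving out each library in turn. Mitochondrially encoded transcripts and several immunoglobulin and T cell receptor constant genes were not analysed here, because the tables used list no values under those symbols.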

Results

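The hippocampal transcriptome was measured in 21 mice, in 2 experiments that set circulating CD8+ T cells of different age, or their removal, against a matched control. Young recipients carried T cells from aged donors (n = 5) or young donors (n = 6), and aged mice received a CD8a antibody (n = 5) or IgG2b (n = 5). Mean depth was 14050000 ± 1096000 reads (SD) in aged T recipients and 13390000 ± 1236000 in young T recipients. It was 10970000 ± 834800 reads with the CD8a antibody and 13130000 ± 1258000 with IgG2b, so antibody-treated libraries were shallower than their controls (exact permutation p = 0.0238). Genes with at least 1 read numbered 16380 ± 178 in aged T recipients, 16370 ± 168 in young T recipients, 16190 ± 137 with the antibody and 16270 ± 106 with IgG2b.

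The first question was what T cells from aged donors change in a young hippocampus. Transcripts of energy metabolism and translation lay slightly higher in aged T recipients, and transcripts of vessel wall and meningeal fibroblasts lay lower, but no single gene passed the test. Of 90 tested nuclear genes of oxidative phosphorylation, the mitochondrial machinery that makes ATP, 88 were higher, with a median log2 difference of 0.28. Of 17 markers of meningeal and vascular fibroblasts, the collagen-producing cells of the brain's coverings and vessels, 17 were lower, with a median of -0.61 (-0.40 without young T replicate 1). With the correlation estimated from the data, no list passed (adjusted p = 0.725 for the oxidative phosphorylation, ribosomal protein, pericyte and fibroblast lists). Subtracting the trend of log2 difference with transcript length left a median of 0.09 of 0.28 over 176 oxidative phosphorylation and ribosomal protein genes. That trend ran across 14074 genes (Spearman rho -0.46, shorter transcripts higher), and the lists that lay lower were not tested against it. The genes with the smallest p were the ribosomal RNA precursor Rn45s (127500 ± 31600 against 61650 ± 24150 normalized counts, SD, n = 5 and 6) and Nav2, a neuron navigator gene (334 ± 40.6 against 471 ± 51.1).

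Among 14162 genes tested, limma called 0 at an adjusted p under 0.05, and 1169 had an unadjusted p under 0.05, 608 higher and 561 lower. edgeR, DESeq2 and limma-voom also called 0, with 1263, 1478 and 1165 genes at an unadjusted p under 0.05, and the authors' deposited table called 0 with 1478. The smallest adjusted p was 0.600 with limma, and in the authors' deposited table it was 0.0899, for Nav2. The 5 genes with the smallest p on the higher side did not pass. They were Rn45s (log2 difference 1.09, SE 0.22), Romo1, a mitochondrial inner membrane protein (0.56, SE 0.13), Iscu, an iron-sulfur cluster scaffold (0.31, SE 0.08), Fam58b (0.48, SE 0.12) and Smco3 (0.41, SE 0.10). The 5 on the lower side did not pass either. They were Nav2 (-0.50, SE 0.10, at 48959063 to 49610090 of chromosome 7), the imprinted antisense RNA Kcnq1ot1 (-0.87, SE 0.20), the transcriptional repressor Hic2 (-0.63, SE 0.14), the lipoprotein receptor Lrp1 (-0.40, SE 0.10) and the cyclin Ccnt1 (-0.43, SE 0.10). Each of these 10 genes lay on the same side of the young T median in all 5 aged T libraries, and limma's adjusted p was 0.600 for each.

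With the preset correlation, 11 of 36 lists passed in the transfer, 5 with higher and 6 with lower values. Oxidative phosphorylation genes passed, with Ndufb3 at 1189 ± 196 against 908 ± 82.4 normalized counts and Ndufb10 at 1424 ± 187 against 1092 ± 147. For this list the camera adjusted p was 2.08e-22, and the adjusted p was 0.725 with an estimated correlation. Cytosolic ribosomal protein genes passed with 90 of 96 members higher and a median of 0.27 (camera adjusted p = 3.33e-16, and adjusted p = 0.725 with an estimated correlation). The name pattern of that list also takes 10 kinases of ribosomal protein S6, which are not ribosomal proteins. Without them, 86 of 86 members were higher, including Rpl19. The share of reads from Rn45s was 0.936 ± 0.235% in aged T and 0.452 ± 0.173% in young T recipients (exact permutation p = 0.00649). Like both lists it was higher in aged T recipients. Within groups, the Rn45s level and the genes of both lists had a correlation of -0.143 (interval -0.709 to 0.535). Without the trend with transcript length, fitted on the other genes, the median over both lists (kinases left out) was 0.09 instead of 0.28. Myelin genes passed with 21 of 22 higher and a median of 0.33, among them Cldn11, a tight junction protein of myelin, and Car2, a carbonic anhydrase. The list had a camera adjusted p of 4.16e-06, and the adjusted p was 0.725 with an estimated correlation. Ependymal markers passed with 11 of 13 higher and a median of 0.38, led by Ccdc153 and Mia (camera adjusted p = 0.00101, and adjusted p = 0.725 with an estimated correlation). Activated microglia genes passed with 15 of 19 higher and a median of 0.15, with Tyrobp, a microglial receptor adaptor, at 107 ± 29 against 75.4 ± 23.6. Their camera adjusted p was 0.0342, and the adjusted p was 0.725 with an estimated correlation. Single libraries moved some of these medians by over 1.5 times, the ribosomal one to 0.15 without aged T replicate 3, the microglial one to 0.24 and the ependymal one to 0.68 without aged T replicate 4, and the latter to 0.57 without young T replicate 1. Of the members of these 5 lists, 0 were called by limma over all genes and 0 when adjusted over the list alone.

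On the lower side, fibroblast markers passed, with Lum, a matrix proteoglycan, at 52.6 ± 14.9 against 83.1 ± 20.1 normalized counts and Slc22a6 at 36.8 ± 16.8 against 88.4 ± 50.8. For this list the camera adjusted p was 1.70e-05, and the adjusted p was 0.725 with an estimated correlation. Pericyte and smooth muscle markers passed with 12 of 13 lower and a median of -0.31, including the contractile genes Myh11 (167 ± 94.7 against 337 ± 154) and Tagln. The list had a camera adjusted p of 0.000151, and the adjusted p was 0.725 with an estimated correlation. Extracellular matrix genes passed with 17 of 20 lower and a median of -0.37, including Fn1 and Col4a2 (camera adjusted p = 0.00084, and adjusted p = 0.725 with an estimated correlation). Endothelial markers, with 16 of 19 lower and Vwf at 231 ± 73.7 against 361 ± 130, had a median of -0.16 (camera adjusted p = 0.0165, and adjusted p = 0.811 with an estimated correlation). Excitatory synapse genes had 19 of 23 lower and a median of -0.11. Their camera adjusted p was 0.00944, and the adjusted p was 0.725 with an estimated correlation. Presynaptic vesicle genes had 18 of 20 lower and a median of -0.08, including Unc13a and Pclo of the release site (camera adjusted p = 0.0273, and adjusted p = 0.811 with an estimated correlation). Without aged T replicate 4 the median was -0.09 for endothelial, -0.17 for excitatory synapse and -0.15 for presynaptic genes, and without aged T replicate 5 it was -0.24 for extracellular matrix, -0.07 for excitatory synapse and -0.04 for presynaptic genes. Without young T replicate 1 it was -0.40 for fibroblast, -0.23 for extracellular matrix and -0.08 for endothelial genes, and without young T replicate 3 it was -0.13 for presynaptic genes. Of the members of these 6 lists, 0 were called over all genes and 0 when adjusted over the list alone. Whether the trend with transcript length plays a part in these 6 lists was not tested. fry called 0 of the 36 lists, with 2 at an unadjusted p under 0.05, and the exact permutation test of list values called 0, with 1 at an unadjusted p under 0.05.

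Single libraries ended 5 of the 11 list calls of the transfer. Activated microglia genes did not pass without aged T replicates 1, 3 or 5 or young T replicate 2 (camera adjusted p up to 0.157, medians 0.18, 0.13, 0.10 and 0.15 against 0.15), and ependymal markers did not pass without aged T replicate 2 (0.0555, median 0.26 against 0.38). Presynaptic vesicle genes did not pass without aged T replicates 1 or 5 or young T replicates 2, 5 or 6 (camera adjusted p up to 0.224, medians -0.06, -0.04, -0.07, -0.06 and -0.06 against -0.08), nor with choroid plexus expression as a covariate (0.0592, median -0.06). Excitatory synapse genes did not pass without aged T replicate 2 or young T replicate 2 (0.0694 and 0.0515), although their median was -0.11 and -0.10 there against -0.11. Endothelial markers did not pass without aged T replicate 4 or young T replicates 1 or 3 (up to 0.370, medians -0.09, -0.08 and -0.13 against -0.16).

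Transcripts of the transferred cells themselves were almost unread. Cd8a, the T cell coreceptor, had 0 reads in the 5 aged T libraries and 1 in the 6 young T libraries, and Cd8b1 likewise 0 and 1. Cd3e, of the T cell receptor complex, had 0 and 7 reads, all 7 in 1 library. Gzmk, the granule protease granzyme K, had 0 and 4 reads, and Gzmb, granzyme B, 2 and 0. A total of 0 reads allows up to 0.0427 CPM in the aged T group and 0.0373 in the young T group. Gfap, the astrocyte filament gene, was at 7663 ± 2120 against 6522 ± 1731 normalized counts (limma adjusted p = 0.712). B2m, the invariant chain of MHC class I (970 ± 172 against 1026 ± 182, adjusted p = 0.870), and Dcx, a marker of new neurons (175 ± 42.4 against 184 ± 47.7, adjusted p = 0.931), did not pass either, and the sign of B2m and Dcx turned when single libraries were left out. Interferon-stimulated genes had a median of -0.17 with 22 of 34 lower and did not pass (camera adjusted p = 0.0916, and adjusted p = 0.902 with an estimated correlation). They passed without aged T replicate 3 or young T replicates 2, 4 or 5 (medians -0.24, -0.25, -0.18 and -0.20, camera adjusted p = 0.000364, 0.00643, 0.00581 and 0.0428).

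**Figure D1:**
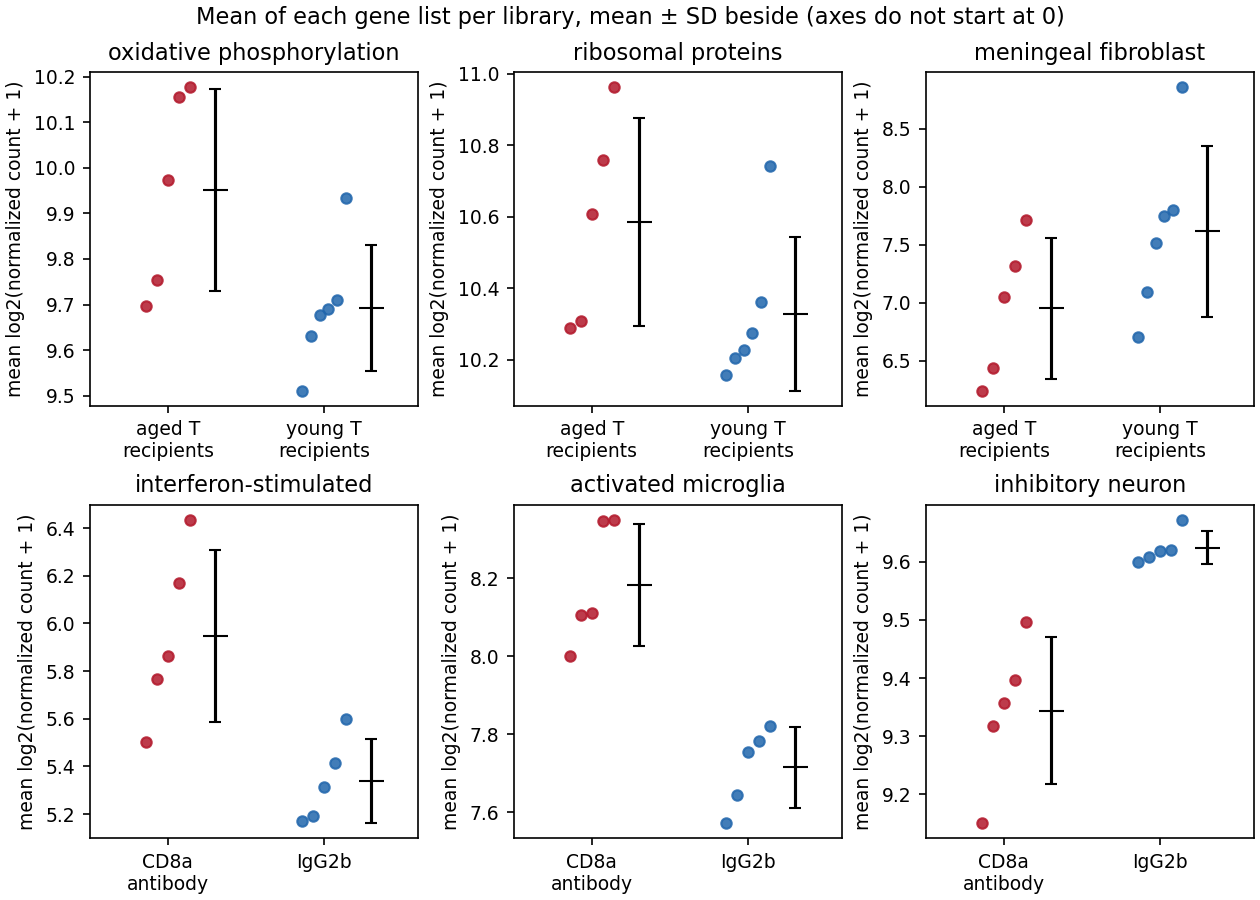
Mean log2(normalized count + 1) over the members of 6 gene lists in each library (1 point per library; the mark beside each group is the mean with SD; axes do not start at 0), with aged T (n = 5) against young T recipients (n = 6) in the upper panels and the CD8a antibody (n = 5) against IgG2b (n = 5) in the lower panels. Oxidative phosphorylation values of aged T (mean 9.95) and young T libraries (9.69) overlapped, whereas activated microglia values with the antibody (8.18) and IgG2b (7.72) did not.

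The second experiment asked what removal of CD8+ T cells changes in an aged hippocampus. Immune and glial genes lay higher with the CD8a antibody, namely interferon-stimulated genes (34 of 36 members, median log2 difference 0.61), activated microglia genes (20 of 23, 0.34) and MHC class II genes (8 of 8, 0.78, and 0.52 without CD8a antibody replicate 3). Inhibitory neuron genes lay lower (18 of 22, median -0.31). With an estimated correlation the adjusted p was 0.00912 for activated microglia genes and 0.0962 for the other 3 lists. Ependymal and choroid plexus markers also lay higher (medians 0.51 and 0.53, adjusted p = 0.303 and 0.740 with an estimated correlation). The choroid plexus median ran from 0.18 to 1.21 without CD8a antibody replicates 3 and 5, and its call held in 3 of the 10 fits without 1 library. A score of 6 ventral minus 4 dorsal hippocampus markers lay lower (log2 difference -0.70, exact permutation p = 0.0159). Gpr101, an orphan G protein-coupled receptor, fell to 88.1 ± 19.5 normalized counts from 238 ± 42.6 with IgG2b (SD, n = 5 each), a log2 difference of -1.43 (SE 0.19, limma adjusted p = 0.0267). The gene lies on chromosome X at 57496668 to 57503757 of mm10.

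Among 13939 genes tested, limma called Gpr101 alone, and 1180 genes had an unadjusted p under 0.05. The call of Gpr101 did not hold without CD8a antibody replicates 1, 3 or 4 or IgG2b replicates 1, 2, 3 or 5 (limma adjusted p up to 0.163), although its log2 difference stayed between -1.53 and -1.29. limma called 0 genes without the mean filter, and 0 with the ventral minus dorsal score as a covariate, an alternative chosen after seeing the data. edgeR and limma-voom each called 1 gene, and DESeq2 called 92, 30 higher and 62 lower, the same 92 as the authors' deposited table. Of those 92 genes, 91 were tested by limma, and all 91 had the same sign and an unadjusted p under 0.05 there. DESeq2 called 303 genes without CD8a antibody replicate 5 and 140 without replicate 2, but 28 without replicate 1 and 25, 32 and 37 without IgG2b replicates 3, 4 and 5. CD8a antibody replicate 5 lay at 57.3 on the first principal component, and the other 4 antibody libraries between -28.2 and -9.97. Without it, limma called 25 genes, 9 higher and 16 lower.

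Genes of antigen presentation had the smallest p on the higher side. Psmb8, an immunoproteasome subunit (chromosome 17, 34198195 to 34201454), was at 97.1 ± 11 against 50.7 ± 8.2 normalized counts (log2 0.93, SE 0.17). B2m (chromosome 2, 122147687 to 122153082) was at 1383 ± 30.9 against 976 ± 107 (0.51, SE 0.09). Both missed the threshold in limma (adjusted p = 0.148) and passed in DESeq2 (adjusted p = 0.00149 and 0.000354). The next genes were Lgals9, an immune lectin (0.65, SE 0.15), Gstt3, a glutathione transferase (0.96, SE 0.22), and Phldb1 (0.62, SE 0.14). Their limma adjusted p was 0.233, and their DESeq2 adjusted p 0.0200, 0.0179 and 0.0205. All 5 antibody libraries lay above the IgG2b median for each of these 5 genes. On the lower side, after Gpr101, stood Tpbg (48.7 ± 8.94 against 106 ± 11.6), Timp2, a metalloproteinase inhibitor (2870 ± 501 against 4740 ± 284), Elavl4, a neuronal RNA-binding protein (740 ± 64.8 against 1177 ± 179), and the procollagen protease Adamts2 (93.9 ± 20.1 against 170 ± 21.8). Their limma adjusted p were 0.079, 0.117, 0.148 and 0.148, and their DESeq2 adjusted p 2.22e-05, 4.51e-05, 0.0002 and 0.00159.

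**Figure D2:**
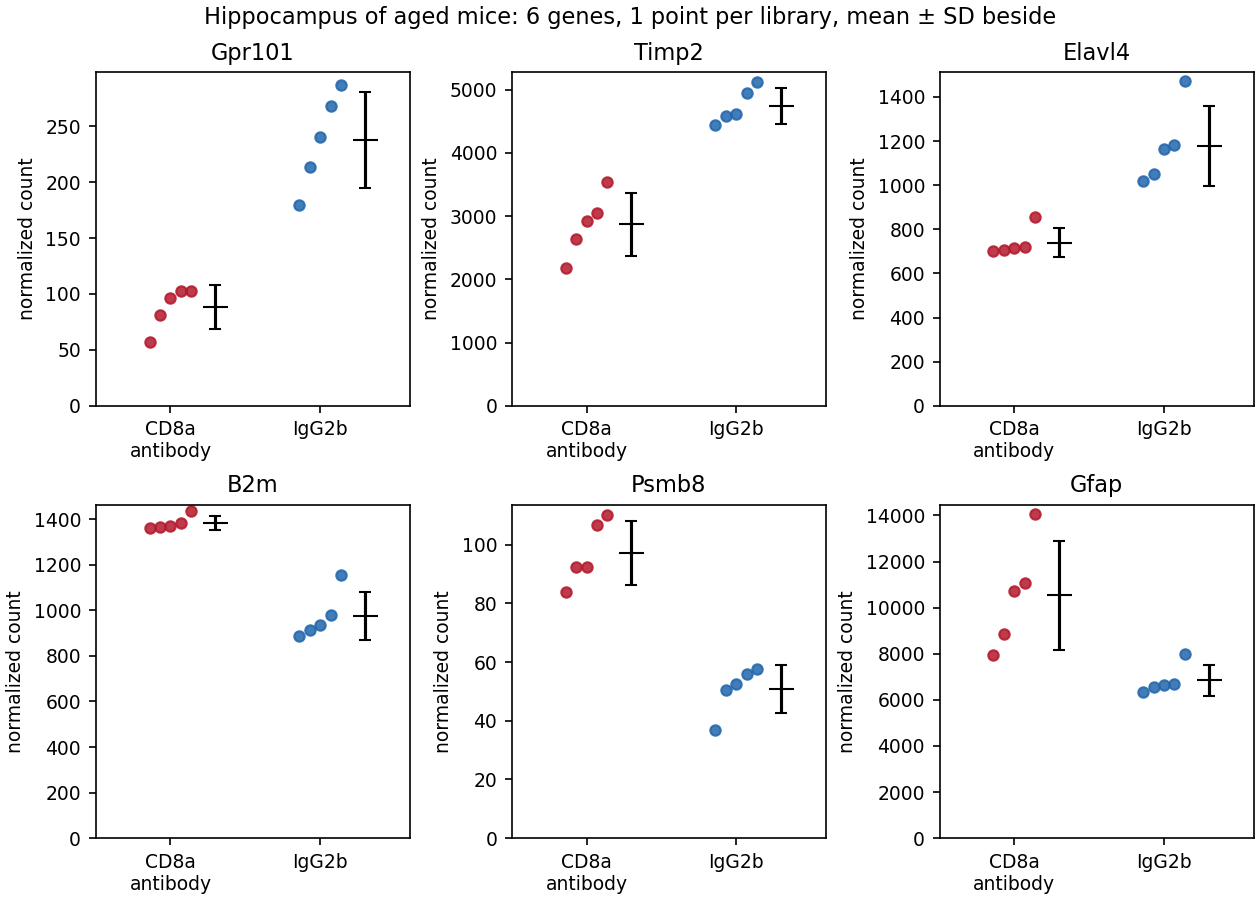
Normalized counts of 6 genes in the hippocampus of aged mice given the CD8a antibody or IgG2b (1 point per library, n = 5 each; the mark beside each group is the mean with SD; axes start at 0). Gpr101, Timp2 and Elavl4 are lower and B2m and Psmb8 higher in all 5 antibody libraries than in any control library, and of the 6 genes limma called Gpr101 and DESeq2 called all 6.

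With the preset correlation, 20 of 36 lists passed in the depletion experiment, 16 with higher and 4 with lower values, and limma called 0 of their members over all genes. Activated microglia genes were the only list that, with all libraries, also passed with an estimated correlation (camera adjusted p = 1.04e-10, and adjusted p = 0.00912 with an estimated correlation). Of 23 members, 7 were called when adjusted over the list alone, with the lysozyme gene Lyz2 at 221 ± 29.6 against 140 ± 27.4 normalized counts and the cathepsin Ctsz at 733 ± 33.2 against 582 ± 56.9. Without CD8a antibody replicate 5, complement and reactive astrocyte genes also passed with an estimated correlation (adjusted p = 0.027 and 0.0322), beside activated microglia genes (0.027). Interferon-stimulated genes passed with a camera adjusted p of 2.34e-14 (adjusted p = 0.0962 with an estimated correlation), and 9 of 36 members were called when adjusted over the list alone. They were led by the interferon signalling factor Irf9 (119 ± 23.1 against 75 ± 7.84) and the guanylate-binding protein Gbp3 (93 ± 52.4 against 33 ± 15.9). MHC class II genes passed (median 0.52 without CD8a antibody replicate 3), led by the cathepsin Ctss and H2-Aa (camera adjusted p = 1.75e-05, and adjusted p = 0.0962 with an estimated correlation). MHC class I genes passed with 16 of 19 higher and a median of 0.21, or 0.34 without CD8a antibody replicate 4 (camera adjusted p = 3.58e-05, and adjusted p = 0.153 with an estimated correlation). Complement genes, with 12 of 14 higher and a median of 0.36, were led by C1qc and C1qb of the initiating complex (camera adjusted p = 0.00087, and adjusted p = 0.0962 with an estimated correlation). Homeostatic microglia genes had 14 of 15 higher and a median of 0.27 (0.18 without CD8a antibody replicate 1), including Fcrls (camera adjusted p = 3.19e-05, and adjusted p = 0.168 with an estimated correlation). Reactive astrocyte genes had 14 of 19 higher and a median of 0.36 (camera adjusted p = 7.02e-05, and adjusted p = 0.117 with an estimated correlation). Gfap was at 10540 ± 2368 against 6847 ± 661 (limma adjusted p = 0.245, DESeq2 adjusted p = 0.0133). Adjusted over the list alone, 5 members of the MHC class I list, 4 each of the MHC class II, complement and reactive astrocyte lists and 1 of the homeostatic microglia list were called.

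Lists of other cell types also lay higher with the antibody. Myelin genes were higher in 22 of 22 members with a median of 0.41, including Opalin, a marker of mature oligodendrocytes, at 394 ± 101 against 196 ± 87.5 normalized counts. For this list the camera adjusted p was 1.95e-08, and the adjusted p was 0.262 with an estimated correlation. Pericyte and smooth muscle markers had 9 of 12 higher and a median of 0.39, led by Acta2 and Myl9 of the contractile apparatus (camera adjusted p = 0.00089, and adjusted p = 0.172 with an estimated correlation). Endothelial markers had a median of 0.22 with 16 of 19 higher, led by the receptor Tie1, although the lipid transporter Mfsd2a was at 133 ± 23.6 against 222 ± 75. The list had a camera adjusted p of 0.00283 (0.163 without CD8a antibody replicate 2, with a median of 0.06), and the adjusted p was 0.355 with an estimated correlation. Dentate gyrus markers had a median of 0.34 (0.23 without CD8a antibody replicate 4 and 0.53 without replicate 5) with 10 of 12 higher, including Plk5 and Tdo2 (camera adjusted p = 0.000844, and adjusted p = 0.338 with an estimated correlation). Ribosomal protein genes had 86 of 97 higher and a median of 0.26 (0.15 without CD8a antibody replicate 2 and 0.17 without replicate 5), including Rps19 (camera adjusted p = 2.71e-10, and adjusted p = 0.487 with an estimated correlation). Oxidative phosphorylation genes had a median of 0.09 with 72 of 89 higher (camera adjusted p = 0.00303, and adjusted p = 0.740 with an estimated correlation). That median was -0.02 without CD8a antibody replicate 5, and 0.06 without IgG2b replicate 4, and both ended the call (camera adjusted p = 0.205 and 0.0972), whereas it was 0.14, 0.16 and 0.16 without CD8a antibody replicates 1, 3 and 4. Adjusted over the list alone, 2 pericyte genes and 1 gene each of the myelin, endothelial and dentate lists were called, and 0 of the ribosomal and oxidative phosphorylation lists.

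Markers of neighbouring tissue moved with the antibody as well. Ependymal markers, with 12 of 12 higher and a median of 0.51, included Tm4sf1 and Rarres2 (camera adjusted p = 3.58e-05, and adjusted p = 0.303 with an estimated correlation). Choroid plexus markers had 19 of 19 higher and a median of 0.53 (camera adjusted p = 0.0356, and adjusted p = 0.740 with an estimated correlation). Ttr, their most abundant transcript, was at 14940 ± 13310 against 7158 ± 10040 normalized counts. The choroid plexus call was lost without CD8a antibody replicates 1, 2 or 3 or IgG2b replicates 2, 3, 4 or 5 (camera adjusted p up to 0.584). Their median was 0.19 and 0.18 without CD8a antibody replicates 2 and 3, and 0.97, 1.21 and 1.05 without CD8a antibody replicates 4 and 5 and IgG2b replicate 1. Fibroblast markers had a median of 0.33 with 15 of 17 higher (camera adjusted p = 0.0356, and adjusted p = 0.645 with an estimated correlation), and were lost without CD8a antibody replicates 2 or 3 or IgG2b replicates 4 or 5 (up to 0.641, with a median of 0.13 without CD8a antibody replicate 3). With choroid plexus expression as a covariate the fibroblast median was 0.24 and the list did not pass (camera adjusted p = 0.196). In the same list Dcn, a proteoglycan, was at 350 ± 151 against 803 ± 128, lower by DESeq2 (adjusted p = 0.00185). Neocortex markers had 13 of 15 lower and a median of -0.27, including Fezf2 and Nxph4 (camera adjusted p = 0.0049, and adjusted p = 0.255 with an estimated correlation), and were lost without IgG2b replicate 1 (0.0941, median -0.15), with a median of -0.12 without CD8a antibody replicate 5. Adjusted over the list alone, 1 gene each of the ependymal and fibroblast lists was called, and 0 of the choroid plexus and neocortex lists.

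Inhibitory neuron genes lay lower, led by the cannabinoid receptor Cnr1 (2091 ± 432 against 3148 ± 361 normalized counts) and Reln, the extracellular guidance protein reelin (349 ± 72.5 against 507 ± 104). This list had a camera adjusted p of 5.33e-06, an adjusted p of 0.0962 with an estimated correlation and a fry adjusted p of 0.0418. Of 22 members, 4 were called when adjusted over the list alone. Presynaptic vesicle genes had 19 of 20 lower and a median of -0.18 (-0.12 without CD8a antibody replicate 2), with the vesicle glycoprotein Sv2b at 4954 ± 776 against 7192 ± 1127. Their camera adjusted p was 0.00087, and the adjusted p was 0.153 with an estimated correlation, with 1 member called when adjusted over the list alone. Glucocorticoid-responsive genes had 15 of 19 lower and a median of -0.28, including Nfkbia and Zbtb16 (camera adjusted p = 0.00442, and adjusted p = 0.487 with an estimated correlation). They had 0 members called over the list alone and were lost without IgG2b replicate 3 (camera adjusted p = 0.117, median -0.19). The exact permutation test of list values called 0 of the 36 lists after adjustment, with 9 at an unadjusted p under 0.05, and fry called 3, activated microglia, MHC class II and inhibitory neuron genes. Without CD8a antibody replicate 5, picked after the data were seen, fry called 10. The exact test's adjusted p was 0.0408 there for interferon-stimulated, activated microglia, homeostatic microglia, reactive astrocyte, inhibitory neuron, complement and presynaptic vesicle genes.

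Depletion of the T cells could not be read from the tissue. Cd8a had 14 reads in the 5 antibody libraries and 10 in the 5 IgG2b libraries (0.261 ± 0.16 and 0.164 ± 0.161 CPM, exact permutation p = 0.397). Gzmk had 0 reads in all 10 libraries, which allows up to 0.0547 CPM with the antibody and 0.0457 with IgG2b. C4b, a complement gene, was at 2023 ± 741 against 1196 ± 155 normalized counts (limma adjusted p = 0.425, and 0.0225 without CD8a antibody replicate 5). H2-K1, an MHC class I gene, was at 568 ± 96.2 against 393 ± 87.8, and Cd74, the MHC class II invariant chain, at 64.2 ± 41.1 against 26.4 ± 3.44. Dcx was at 83.4 ± 31.2 against 112 ± 25.6. The limma adjusted p of these 3 genes were 0.324, 0.459 and 0.622.

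**Figure D3:**
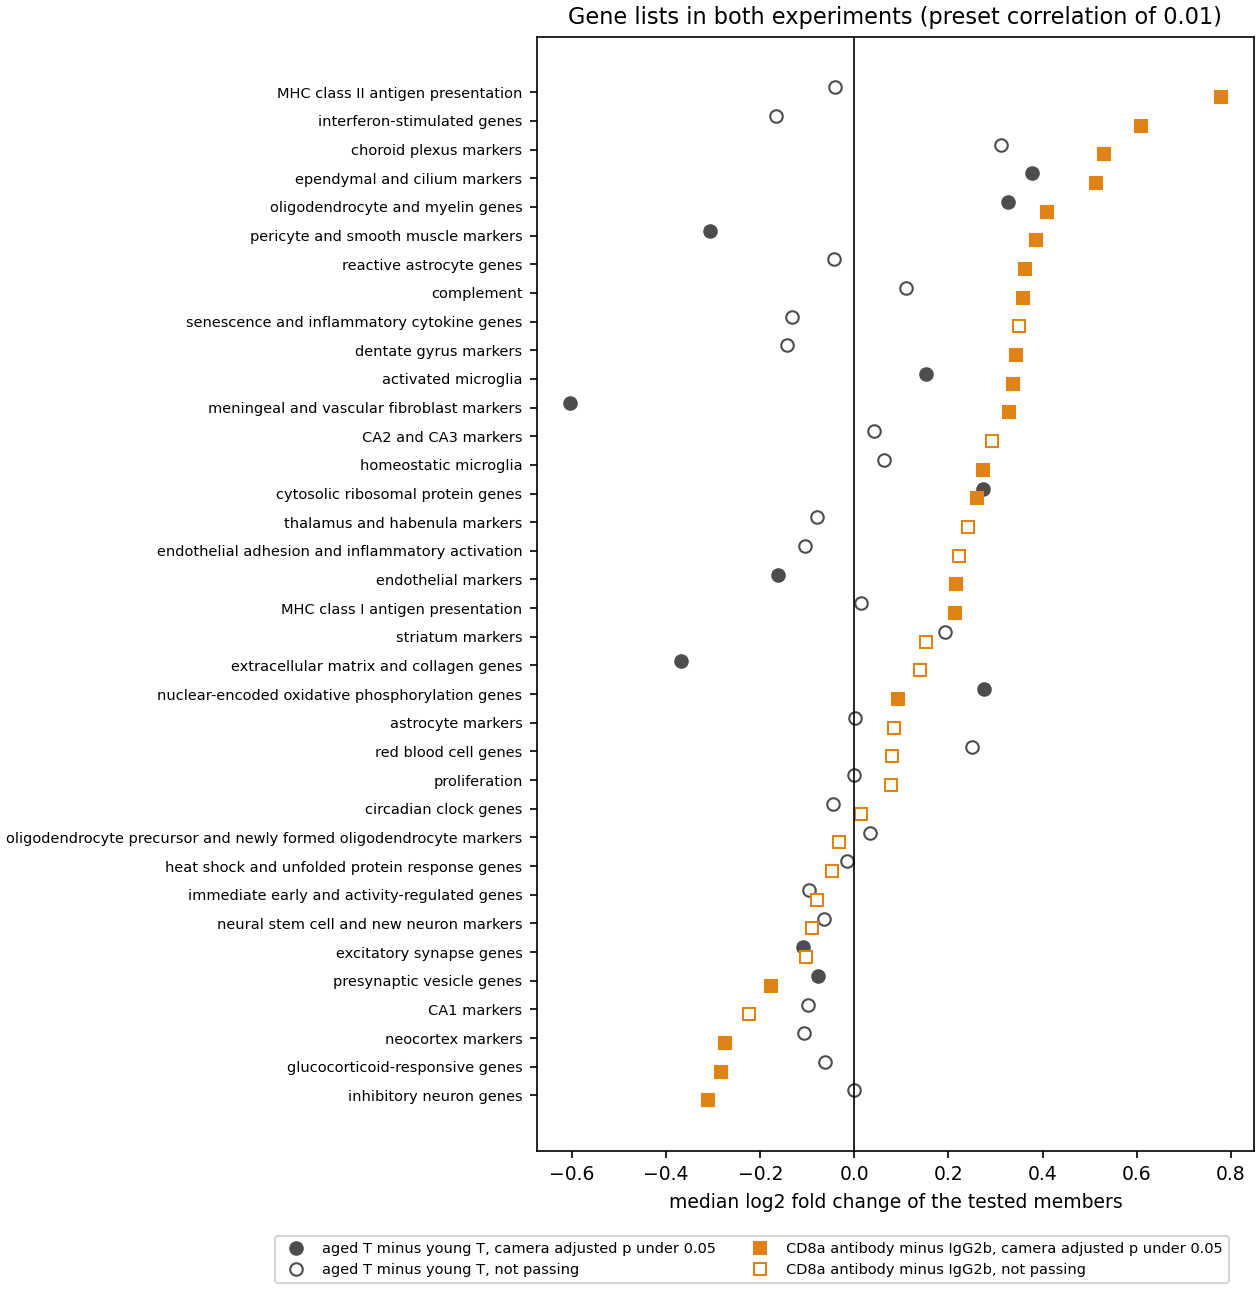
Median log2 fold change of the tested members of 36 gene lists in both experiments (circles, aged T minus young T; squares, CD8a antibody minus IgG2b; filled where camera with the preset correlation of 0.01 gave an adjusted p under 0.05). Interferon-stimulated genes stand at -0.17 in the transfer and 0.61 in the depletion, and meningeal fibroblast markers at -0.61 and 0.33, and the difference between experiments was not tested.

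The design sets the depletion as the converse of the transfer, so the experiments were compared gene by gene. A converse would give a negative correlation and mostly opposite signs. Over 13864 genes tested in both, log2 fold changes had a Spearman rho of 0.20 across genes, which are not independent replicates. Among 100 groupings of the depletion libraries, the real one included, the permutation p was 0.71, and the others gave from -0.33 to 0.36. Without CD8a antibody replicate 5 rho was -0.01, and it was 0.08 and 0.14 without aged T replicate 5 and young T replicate 6. Of the 88 genes with an unadjusted p under 0.05 in both, 65 had the same sign and 23 the opposite sign, and 96.9 such genes are expected if the experiments are independent. A positive rho and mostly shared signs are not what a converse gives, but the permutation p of rho leaves the direction undecided. The 100 genes with the smallest p on the higher side in aged T recipients had a median of 0.09 in the depletion, 73 of them higher with the antibody (camera adjusted p = 0.00219, and adjusted p = 0.969 with an estimated correlation). That median was -0.03 without CD8a antibody replicate 5, and 0.06 without IgG2b replicate 4, with the call lost in both (camera adjusted p = 0.213 and 0.0702), and 0.14 without CD8a antibody replicate 3. The 100 genes on the lower side had a median of -0.003 (camera adjusted p = 0.874), which turned to 0.09 and passed without CD8a antibody replicate 5 (camera adjusted p = 0.0053), and turned to 0.0159 and 0.0049 without IgG2b replicates 4 and 5. In the transfer, the depletion-higher genes had a median of 0.03 and the depletion-lower genes -0.04 (for both, camera adjusted p = 0.324, and adjusted p = 0.806 with an estimated correlation). With the preset correlation, both passed without aged T replicate 4 (0.00223 for both) or young T replicate 1 (0.00789 for both), and the depletion-lower genes also without aged T replicate 1 (0.0183). The depletion-higher median turned to -0.0062, -0.0164 and -0.0416 without aged T replicates 3 and 5 and young T replicate 6, and the depletion-lower median to 0.042 and 0.0165 without the last 2.

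**Figure D4:**
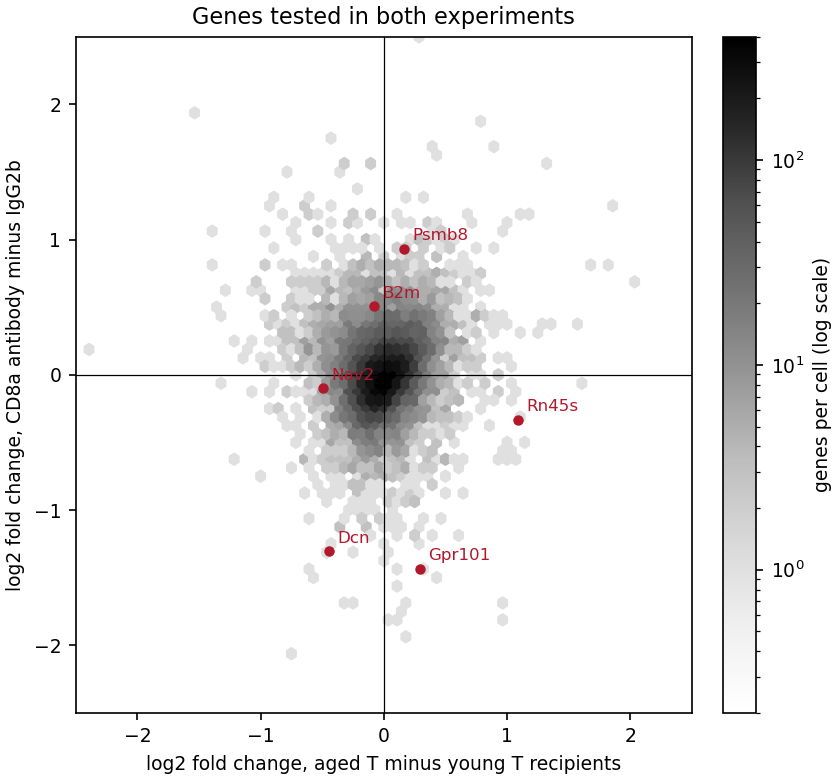
Log2 fold change of each gene tested in both experiments, aged T minus young T recipients (x axis) against CD8a antibody minus IgG2b (y axis), as genes per hexagonal cell on a log colour scale, with 6 genes marked and 5 genes outside the drawn range. Psmb8 and B2m lie higher with the antibody (0.93 and 0.51) than in the transfer (0.16 and -0.08), and the cloud has the weak rho of 0.20.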

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

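In each group of 5 or 6 libraries, the highest or lowest library was compared with the others by Dixon's test (genes on the log2 scale), over 354 groups of values, and 27 stood apart. Chance alone sets apart about 1 in 20 groups. The tests of residual blood and of 1 library for the interferon and microglia pattern were chosen after their results were seen. So were the ventral covariate fits, the leave-one-out fits of DESeq2 and of inhibitory neuron genes, and the interval of the Rn45s correlation.

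In the transfer, aged T replicate 4 stood lowest in H2-K1, an MHC class I gene, at 253.5 normalized counts (the others 444.4 to 529). The same library stood lowest in the mean log2 value of MHC class II genes, at 4.398 (5.431 to 5.783), and of endothelial markers, at 7.866 (8.212 to 8.329). Aged T replicate 2 stood highest in oligodendrocyte precursor markers at 8.565 (8.211 to 8.311). Young T replicate 2 stood highest in Rn45s at 109700 normalized counts (46440 to 62120), or 0.7952% of reads (0.3503 to 0.4666). Young T replicate 3 stood highest in Rpl19 at 3591 normalized counts (2168 to 2616) and in ribosomal protein genes at 10.74 (10.16 to 10.36). Young T replicate 5 stood lowest in senescence and cytokine genes at 6.379 (6.873 to 7.16) and in circadian clock genes at 8.952 (9.285 to 9.412), and highest in haemoglobin at 0.004623% of reads (0.0005835 to 0.001638).

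With the CD8a antibody, replicate 5 stood apart on the first principal component at 57.3 (the others -28.18 to -9.968), and stood lowest in ependymal markers at 4.415 (5.55 to 5.934) and in senescence and cytokine genes at 5.988 (6.327 to 6.466). Replicate 2 stood highest in B2m at 1436 normalized counts (1361 to 1381) and in the lipid transporter Mfsd2a at 174.9 (120.5 to 128.5), and lowest in CA2 and CA3 markers at 8.21 (8.662 to 8.698). Replicate 3 stood highest in Elavl4 at 855.2 (703.1 to 719.5). With IgG2b, replicate 1 stood lowest in CA2 and CA3 markers at 7.77 (8.617 to 8.754), and highest in Ttr at 0.2116% of reads (0.01326 to 0.03174) and in Dcn at 1032 normalized counts (732.9 to 769.5). It also stood highest in inhibitory neuron genes at 9.672 (9.6 to 9.62) and in endothelial markers at 7.648 (7.552 to 7.579). IgG2b replicate 2 stood highest in Gfap at 8001 normalized counts (6335 to 6709). IgG2b replicate 5 stood lowest in H2-Aa at 1.073 (5.868 to 9.496) and highest in Rn45s at 1.716% of reads (0.9053 to 1.113). IgG2b replicate 4 stood highest in haemoglobin at 0.01224% of reads (0.0004503 to 0.001473).

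After thinning all libraries to equal depth, the median of the 62 genes that DESeq2 called lower with the antibody was 1.02 times that before. Random thinning keeps ratios between libraries on average, so a value near 1 was fixed beforehand. It does not decide whether depth played a part for the 62 genes. That they kept at least 0.943 of their median without any 1 library decides nothing, as they were picked using all libraries. DESeq2's 92 calls fell to 28 without CD8a antibody replicate 1 and to 25, 32 and 37 without IgG2b replicates 3, 4 and 5. The inhibitory neuron list, whose members were written beforehand, kept at least 0.828 of its difference (without CD8a antibody replicate 2). The bound for that test was set with its result known, so it does not decide whether 1 library explains the list. Control dissections that hold more ventral hippocampus stay open as an explanation of the 62 genes, since the ventral minus dorsal score differed by -0.701 (exact permutation p = 0.0159), with 6 of 6 ventral markers lower and 2 of 4 dorsal markers higher. With that score as a covariate DESeq2 still called 7 of the 62 genes and all 62 kept their sign, while their median went from -0.63 to -0.58 and the median SE from 0.148 to 0.212, so calls ended mainly by the wider SE of a score and group that share their spread (r = -0.716), and the 2 cannot be told apart. Within groups, the score and the mean of the 62 genes had a correlation of 0.535 in the depletion and 0.56 in the transfer. Over all 11 transfer libraries the Pearson correlation was 0.531 (permutation p = 0.0944). The effect of the antibody is the biological explanation that the design names, and it is not separated from dissection here.

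Interferon-stimulated genes were higher with the antibody by 0.61, which kept 0.862 of its value with choroid plexus expression as a covariate (0.53, SE 0.13) and 0.92 with red blood cell expression (0.56, SE 0.20), and at least 0.801 without any 1 library, the lowest being without CD8a antibody replicate 2. The activated microglia difference of 0.47 was 0.47 (SE 0.09) and 0.49 (SE 0.09) with these covariates, and kept at least 0.91 of its value without any 1 library, the lowest being without CD8a antibody replicate 1. Choroid plexus tissue is therefore argued against as the whole explanation. The bounds for blood and for 1 library were set with their results known. The shares kept in those tests are therefore described only and do not decide. A response to the antibody treatment, whether through loss of CD8+ T cells or through the antibody itself, may account for the pattern as a hypothesis, and the design does not separate these. With the ventral minus dorsal score as a covariate the 2 differences were 0.66 (SE 0.27) and 0.42 (SE 0.13), and no other technical explanation was tested.

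The higher oxidative phosphorylation and ribosomal protein genes in aged T recipients go with transcript length. Across genes, which are not independent, log2 fold change and length had a Spearman rho of -0.46 (permutation p = 0.01, the smallest that 100 groupings can give), and the set had a median length of 737 bases against 2368. Subtracting the length trend left 0.326 of the set's median (0.315 and 0.345 with other spans of the fit), a value at the bound of 0.33 set beforehand. The bootstrap interval of 0.292 to 0.374 resampled genes with the trend held fixed, so it does not cover the spread between mice. A length bias of the libraries is a candidate explanation for most of the pattern but not shown for all. The trend ran across all genes with a known length, and its part in the lists that lay lower was not tested. Residual ribosomal RNA stays open, because its correlation with the set within groups was -0.143 over 11 libraries with an interval of -0.709 to 0.535. The age of the donor T cells is the biological explanation the design names, untested against these.

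Other splits of the same libraries bear on each count, with 100 splits drawn and the real one included. In the transfer limma called 0 genes, so every split must give as many (100 of 100, up to 22), and the splits say nothing about that count. There 51 of 100 gave as many lists as the real 11, up to 24, so chance is not excluded for the lists. limma's unadjusted p was under 0.05 for 1169 genes there, and edgeR and DESeq2 also called 0. In the depletion, 6 splits gave as many limma calls as the real 1, up to 12, and 5 gave as many lists as the real 20, up to 23, so chance is not excluded for either. For DESeq2, 3 splits gave as many as the real 92, the real one and 2 others with 107 and 199. This is under the share of 0.05 set beforehand, with no adjustment over the counts compared here. Chance is therefore made less likely for this count but is not excluded. Why those 2 gave more was not tested.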

How the results depend on the processing

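Alternatives chosen after the data were seen were edgeR with trimmed-mean scaling, other scalings of the limma fit, exact permutation of list values, the ribosomal list without kinases, the ventral minus dorsal covariate, and the DESeq2 leave-one-out and thinned fits. All others were planned. edgeR without a filter was planned and run, and its counts are not reported here.

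In the transfer, the 0 genes called stayed 0 in the 13 other fits reported here and without any 1 library (0 to 0). Genes at an unadjusted p under 0.05 numbered 1169 in limma, 1263 in edgeR and 1478 in DESeq2. Lists went from 11 to 0 with an estimated correlation, 0 with fry and 0 with exact permutation, and from 9 (without aged T replicate 1) to 13 (without young T replicate 5). In the depletion, the 1 gene called became 92 with DESeq2 (30 higher, 62 lower), 3 with the choroid plexus covariate, 0 with the ventral minus dorsal covariate and 0 without the mean filter, where more genes are tested. Leaving out single libraries gave 0 for 7 of them, CD8a antibody replicate 1 among these, and at most 25, without CD8a antibody replicate 5. DESeq2's 92 ranged from 25 (without IgG2b replicate 3) to 303 (without CD8a antibody replicate 5), and were 78 in thinned libraries, 75 of them shared, and 41 with the ventral minus dorsal covariate, 9 of them shared. Lists went from 20 to 1, 3 and 0 with an estimated correlation, fry and exact permutation. With the preset correlation they ranged from 17 (without CD8a antibody replicate 2) to 22 (without replicate 5). Without replicate 5, a library picked after the data were seen, an estimated correlation gave 3 lists and fry 10. The smallest adjusted p of the exact permutation test was 0.0408 there. These 3 tests were not run without other single libraries. Other scalings moved the median of all genes by at most 0.0044.

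The transfer-higher genes (median 0.0944 in the depletion) did not pass with an estimated correlation (adjusted p = 0.969) or fry (0.951), and ranged from -0.0255 (without CD8a antibody replicate 5) to 0.1449, with the call lost at the lowest value and without IgG2b replicate 4 (0.061, camera adjusted p = 0.0702). The transfer-lower genes turned to 0.0018 with 50 and 0.0076 with 200 genes, and ranged from -0.0421 to 0.0873. The highest value, without CD8a antibody replicate 5, passed (camera adjusted p = 0.0053). The depletion-lower genes passed with 200 genes (-0.0634, camera adjusted p = 0.0321) and ranged from -0.1153 (without aged T replicate 4) to 0.042 (without aged T replicate 5). They also passed without aged T replicate 1 (-0.1083, camera adjusted p = 0.0183), aged T replicate 4 (0.00223) and young T replicate 1 (-0.0805, 0.00789). The depletion-higher genes ranged from -0.0416 (without young T replicate 6) to 0.0915 (without aged T replicate 4), and passed without aged T replicate 4 (camera adjusted p = 0.00223) and young T replicate 1 (0.0875, 0.00789). The correlation between experiments ranged from -0.0102 (without CD8a antibody replicate 5) to 0.302. The cause was not tested for any of these.

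Among named results that turned, Ttr was at -0.0541 in the transfer and -0.1002 in the depletion with the choroid plexus covariate, which holds Ttr itself, and none of the turned genes was called. Without single libraries, transfer values ranged from -0.1847 to 1.0645 for Ttr, -0.1384 to 0.0894 for C4b, -0.1576 to 0.005 for B2m, -0.1344 to 0.1354 for H2-K1 and -0.1706 to 0.0711 for Dcx. Oxidative phosphorylation genes in the depletion ranged from -0.0183 (without CD8a antibody replicate 5) to 0.1613. Counting each named gene or list with each alternative, direction and side of the threshold were kept 625 times and turned 15 times for transfer genes, and kept 756 times for depletion genes, with 29 gained, 7 lost and 1 turned. For lists they were kept 138 times and lost 49 times in the transfer, and kept 246 times, lost 72 times and turned 1 time in the depletion.

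Depth limits the T cell transcripts, with floors of 0.0373 to 0.0547 CPM per group. In simulation limma recovered 29% of 1.5-fold changes in the depletion design and 58% in the transfer design.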

Other observations

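The enrichment tests, the summed reads of untested markers and the imprinted gene hypothesis were chosen after the called genes were seen. Among the 30 genes that the authors' deposited table calls higher with the CD8a antibody, reactive astrocyte genes were over-represented (Gfap, Psmb8 and Ptx3, Fisher's exact test, adjusted p = 0.000412). So were pericyte and smooth muscle markers (Acta2 and Myl9, 0.00519), MHC class I genes (B2m and Psmb8, 0.00887) and interferon-stimulated genes (Gbp3 and Irf9, 0.024). These tests treat genes as independent and rest on 2 or 3 called genes each, with Psmb8 counted in both of its lists. With an estimated correlation, the camera adjusted p of these lists was 0.117, 0.172, 0.153 and 0.0962 in the same order. In the same authors' deposited table, no list was over-represented among the 62 genes called lower (smallest adjusted p = 0.558). Those 62, named here after their values were seen, include the tachykinin receptor Tacr3 (log2 -1.67 in the authors' deposited table), the somatostatin receptor Sstr1 (-0.93), the NMDA receptor subunit Grin3a (-0.71) and the GABA receptor subunit Gabra3 (-0.67). The axon guidance genes Slit2 (-0.74) and Efnb2 (-0.77) are also among them in the authors' deposited table.

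Lists of new neurons, cell division, astrocyte markers and hippocampal fields did not pass in either experiment with all libraries, except dentate gyrus markers in the depletion. Neural stem cell and new neuron markers had a median of -0.06 in the transfer (camera adjusted p = 0.969) and -0.09 in the depletion (0.241), CA1 markers -0.10 (0.408) and -0.22 (0.128), and CA2 and CA3 markers 0.04 (0.408) and 0.29 (0.702). Astrocyte markers had a median of 0.00 (0.969) and 0.08 (0.213). They passed without aged T replicate 3 (-0.10, camera adjusted p = 0.0272) and without CD8a antibody replicate 5 (0.22, 0.00327, but 0.479 with an estimated correlation). Dentate gyrus markers passed in the transfer without young T replicate 1 (-0.22, 0.0308), and CA1 markers in the depletion without IgG2b replicate 2 (-0.25, 0.012). Senescence and cytokine genes stood at -0.13 (0.969) and 0.35 (0.0517). In the depletion they passed without CD8a antibody replicates 3 or 5 or IgG2b replicates 3 or 5 (0.0451, 0.0156, 0.0165 and 0.0416). With an estimated correlation their adjusted p was 0.134 without CD8a antibody replicate 5. Activity-regulated genes stood at -0.10 in the transfer (camera adjusted p = 0.062) and -0.08 in the depletion (0.235). They passed without aged T replicate 2 or young T replicates 1, 3 or 4 (camera adjusted p = 0.0106, 0.0308, 0.00122 and 0.0429) and without CD8a antibody replicate 4 (-0.17, 0.034). Choroid plexus markers in the transfer (0.31, camera adjusted p = 0.385) passed without aged T replicates 3 or 4 or young T replicate 5 (0.77, 0.85 and 0.66). Cell types with fewer than 5 tested markers were compared by summed reads of the untested members. For pan-T cell markers these were 2.28 ± 0.796 CPM in aged T and 1.4 ± 0.753 in young T recipients (exact permutation p = 0.0909), and 2.39 ± 0.608 against 2.04 ± 0.986 in the depletion (exact permutation p = 0.508). For cytotoxic effectors they were 1.88 ± 0.513 against 1.8 ± 0.362 in the transfer (exact permutation p = 0.773) and 3.82 ± 0.756 against 2.79 ± 0.903 in the depletion (exact permutation p = 0.0952).

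A hypothesis drawn from the called genes was that imprinted genes, expressed from 1 parental copy, shift as a group with the antibody. The 62 lower genes hold 6 of 40 imprinted genes with an adjusted p (Dio3, Dlk1, Impact, Mest, Nap1l5 and Plagl1), with 0.177 expected and 0 among the higher genes, but the list of 50 imprinted genes was written after these were seen. Over the 34 tested imprinted genes that were not called, 22 were lower and the mean value differed by -0.14 (exact permutation p = 0.0397). The difference ranged from -0.182 to -0.109 without 1 library, and its exact permutation p was 0.05 or more (up to 0.0873) without any of CD8a antibody replicates 1, 3, 4 or 5 or IgG2b replicates 1, 2, 3, 4 or 5. With the ventral minus dorsal score as a covariate it was -0.05 (SE 0.07), so a group shift may come from dissection, and in the transfer 44 imprinted genes differed by 6e-04 (exact permutation p = 0.994).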
